A study of Mus musculus with 108 samples.

How the data were processed

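Messenger RNA was measured by sequencing in liver, kidney and white adipose tissue of mice labelled Bmal1-flox or Bmal1-iKO at 6 times of day, with 3 libraries per tissue, genotype and time. Per the labels' protocols, RNA was extracted with Trizol, libraries were made with a NEBNext Ultra RNA kit and reads of 150 bp were taken on an Illumina sequencer. The authors deposited 1 table with whole-number read counts per gene, not normalized, for all 108 libraries. Per the submitters' processing notes the tools were HISAT2 2.0.4, featureCounts 1.5.0-p3 and DESeq2 1.16.1, and the genome was GRCm38 (mm10). The order of these steps, their settings and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited counts were used as they are. Of 55416 genes, 1492 have no symbol and keep their identifier, and 108 symbols stand on more than 1 line. Coordinates are those of the deposited table.

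Each library was assigned to its tissue, genotype and time from the labels, and its column was matched by name. Libraries of 1 group were compared with each other for duplication by a chi-square test of their counts over genes, and the lowest chi-square per degree of freedom of the 108 pairs was 10.55, so no pair agreed within sampling noise. Total counts and marker gene means per library were computed before any test. Depth was similar between tissues, and a difference seen here covers counting error and the spread between libraries together.

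The tests, lists, alternatives and the rule for named genes were chosen before the data were examined, except where a sentence says otherwise. Counts of each tissue were filtered with filterByExpr over its 12 groups, scaled with TMM and fitted in edgeR 4.0.16 with 1 mean per genotype and time, under R 4.3.3. Dispersions came from estimateDisp and tests from glmQLFit (robust) and glmQLFTest, adjusted by Benjamini and Hochberg over all genes tested, and a gene is said to be called at an adjusted p under 0.05. The average genotype effect is the mean of the 6 differences of iKO minus flox, the effect at a time is 1 of them, and the interaction is their joint test. The common biological coefficient of variation was 0.514 in liver, 0.302 in kidney and 0.785 in WAT. Log2 CPM values use a prior count of 2.

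Rhythm was tested in a second fit with a mean and a 24 h cosine and sine per genotype. The 2 terms of a genotype were tested jointly for rhythm, and their difference between genotypes for a change of rhythm. Amplitude is the fitted log2 distance from mean to peak, and peak time is in hours after lights on. For the 22 clock genes, changes of peak and amplitude were tested by permuting genotypes within each time in 100000 draws, two-sided, and adjusted over the 66 pairs of gene and tissue for each quantity. The 3 tissues were compared in 1 fit of all libraries with a mean per group, filtered over 36 groups, which left 22789 genes.

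Gene lists were fixed before the data were examined, 34 of pathways and 16 of cell types, with 1062 entries, of which 3 were matched through an older or newer symbol. They were tested with camera of limma 3.58.1 against all other genes tested, with a preset correlation of 0.01 between genes and again with a correlation estimated per list. A list's mean is the mean fitted log2 difference of its tested genes. Genes adjusted over the list alone are counted beside those adjusted over all genes.

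Named genes are the clock genes in each tissue. For the average effect they are also the 10 largest rises and 10 largest falls called with a mean log2 CPM of at least 1 and the same sign at 5 or 6 times. At the time with the most calls they are the 3 largest rises and falls with no overlap of the 3 and 3 libraries, and between tissues the 5 largest differences each way. Changes of rhythm would add the 10 smallest p and the 5 largest gains and losses of amplitude. Up to 4 members with the smallest p stand for each called list. Predicted genes, pseudogenes and clone names are passed over, 2 of them for the liver average.

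Each fit was tested on simulated counts with the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. Dispersions followed the trend over mean expression, and the libraries that stood apart were not imitated. For rhythm the fold is from mean to peak, and a change was a rhythm in iKO with none in flox. Recovery in the real libraries may therefore be lower. Alternatives were DESeq2 1.42.0 in place of edgeR, size factors of DESeq2 in place of TMM, no filter, the replicate number as a block, fits of single times or genotypes, time as a factor, a minimum peak-to-trough ratio of 1.5, and each library left out in turn. Fits without libraries that stood apart were added after the data were seen. These leave out the 11 numbers with a liver cell cycle mean above 2, the 2 numbers with Xist above 3 and Y-linked genes below 0, the 3 numbers with clock offsets of at least 3.5 h in each tissue, and the WAT libraries with marker means above 6. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Some genes that the rule for named genes or a gene list would name are not reported here.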

Results

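RNA was sequenced from liver, kidney and white adipose tissue (WAT) of male C57BL/J mice of 2 genotypes, labelled Bmal1-flox and Bmal1-iKO and written flox and iKO here. Bmal1, whose gene symbol is Arntl, is a transcription factor that the circadian clock of most cells needs. The series title places the clock under study in the intestine and asks about rhythmic metabolism of the liver. The labels do not say in which cells the gene was deleted. Mice lived in a cycle of light and darkness with food and water always present, and tissue was taken at zeitgeber time (ZT, hours after lights on) 2, 6, 10, 14, 18 and 22. Each tissue, genotype and time had 3 libraries, which gives 36 libraries per tissue. Total counts per library (rounded) ran from 14428000 to 23428000 in liver, from 13876000 to 22123000 in kidney and from 14103000 to 24415000 in WAT. The labels give separate samples without saying that each came from its own animal, so p-values measure the spread between these samples, which may be partly technical. Within each group the samples carry the numbers 1 to 3, and a library is named here by genotype, time and number.

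Arntl, the targeted gene, was measured in every group first. In liver its mean rose from 2.69 ± 0.88 CPM (counts scaled to library size, SD, n = 3) at ZT6 to 21.1 ± 5.32 at ZT22 in flox, and ran from 4.36 ± 2.0 at ZT10 to 15.8 ± 4.14 at ZT14 in iKO. Averaged over the 6 times, iKO minus flox was -0.10 on the log2 scale in liver (SE 0.18), 0.28 in kidney (SE 0.21) and -0.09 in WAT (SE 0.22), and edgeR's quasi-likelihood test called none of these differences. Arntl was counted in every library of the 3 tissues, at no less than 1.27 CPM. The gene lies on chromosome 7 from 112806672 to 112913333 of GRCm38. These levels do not check the genotype labels, because the intestine was not measured here and a count over the whole gene does not show which part was deleted.

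Several libraries stood apart from their groups. In liver, 11 libraries had mean log2 CPM over the cell cycle genes of 3.47 to 4.19, against -0.29 to 1.09 in the other 25. They were flox ZT6 1, flox ZT22 1, iKO ZT6 1 and 2, iKO ZT14 1 and 2, iKO ZT18 1 and 2 and iKO ZT22 1, 2 and 3, so 9 of the 11 were iKO and none was from ZT2 or ZT10. The same 11 had macrophage marker means of 6.48 to 8.04 against 1.0 to 5.0, interferon-stimulated gene means of 5.77 to 7.47 against 2.38 to 5.01, and 2.43 to 6.57% of counts from mitochondrially encoded genes against 4.86 to 30.6%. Hepatocyte marker means were 11.1 to 12.5 in the 11 and 11.9 to 12.6 in the 25. In kidney, the libraries of the same genotype, time and number had interferon-stimulated gene means of 4.60 to 6.91 against 1.83 to 4.88. The liver and kidney comparisons below were therefore also run without these 11 numbers, an alternative chosen after the data were seen. It leaves 16 flox and 9 iKO libraries per tissue, with 5 times for the average and 1 iKO library each at ZT6, ZT14 and ZT18. In 2 iKO numbers, ZT18 1 and ZT22 3, liver Xist, a female-specific RNA, stood at 8.55 and 8.72 log2 CPM against at most -0.95 in the others, although the labels call all animals male.

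In liver averaged over the day, some genes of fatty acid synthesis were lower in iKO and some genes of fatty acid oxidation were higher. Neither list as a whole held with an estimated correlation between genes, as given below. Of 26 genes of fatty acid and triglyceride synthesis, 7 fell and none rose. Fasn, the fatty acid synthase, fell by 2.42 on the log2 scale (SE 0.35, adjusted p = 0.00119), from a mean of 915 to 182 CPM over 18 libraries each. Srebf1, the transcription factor that turns on lipid synthesis genes, fell by 1.72 (SE 0.27, adjusted p = 0.00143), Elovl6, a fatty acid elongase, fell by 1.88, and Gpam, which starts triglyceride synthesis, fell by 1.06. Of 35 genes of fatty acid oxidation and ketone synthesis, 6 rose and none fell, among them Cyp4a14 (2.95, SE 0.55, adjusted p = 0.00685), an omega-hydroxylase of fatty acids, and Vnn1 (1.75, SE 0.34, adjusted p = 0.00739), a pantetheinase.

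The gene lists were tested with camera, which compares a list with all other genes tested. The synthesis list was lower (mean log2 difference -0.72, adjusted p = 2.33e-05, and 0.797 with an estimated correlation), and 13 of its genes were lower and 1 higher when adjusted over the list alone. The oxidation list was higher (mean 0.62, adjusted p = 0.000111, and 0.797 estimated; 15 genes higher adjusted over the list alone). Of 23 genes of fatty acid uptake and lipid droplets, 4 rose (adjusted p = 0.00387, and 0.797 estimated; 11 higher and 1 lower adjusted over the list alone), namely Lpl, the lipoprotein lipase (1.46, SE 0.30), Cidea (4.22, SE 1.09) and Plin4 (1.35, SE 0.37) of the lipid droplet surface, and Pnpla2, a triglyceride lipase (0.76, SE 0.20). Cholesterol synthesis was lower as a list (mean -0.50, adjusted p = 0.000273, and 0.797 estimated) with 0 of 23 genes called and 5 lower adjusted over the list alone. Among 42 genes of amino acid breakdown and the urea cycle (adjusted p = 0.000273, and 0.797 estimated; 7 lower adjusted over the list alone), 2 fell, the arginase Arg1 by 1.07 and the glutaminase Gls2 by 0.97. Of 23 immediate early genes 4 rose (adjusted p = 0.000112, and 0.797 estimated; 8 adjusted over the list alone), including Junb by 0.82 and Egr1 by 1.15.

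Lists of dividing and immune cells were higher in the same comparison, in which 9 of the 18 iKO and 2 of the 18 flox liver libraries are among the 11 that stand apart. Of 30 cell cycle genes 4 rose (mean 1.27, adjusted p = 4.27e-12, and 0.797 with an estimated correlation; 23 adjusted over the list alone), including Cenpf of the kinetochore (2.95, SE 0.68) and Bub1b of the spindle checkpoint (2.08, SE 0.53). None of 20 macrophage markers and none of 34 interferon-stimulated genes was called singly, while 18 of each were higher adjusted over the list alone (list adjusted p = 2.54e-06 and 8.82e-06, and 0.797 estimated for each). Of 13 mitochondrially encoded genes 1 fell, mt-Nd4l by 2.40 (list adjusted p = 2.71e-06, and 0.797 estimated; 11 lower adjusted over the list alone). Male-biased liver genes (adjusted p = 0.00129), nuclear genes of oxidative phosphorylation (0.00415), conjugating enzymes and drug transporters (0.0144) and cholangiocyte markers (0.0277) were lower as lists and neutrophil markers (0.0416) higher, with no gene called. All 15 calls among the 42 lists used a preset correlation of 0.01. Each had adjusted p = 0.797 with an estimated correlation, so none held.

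Over all 16582 liver genes tested, 438 differed on average, 180 higher and 258 lower in iKO, and DESeq2 called 1609. Leaving out 1 library gave from 217 (without iKO ZT10 2) to 3259 genes (without flox ZT6 1), and 11 of the 20 genes named next stayed called in all 36 such fits. Without the 2 Xist numbers 201 differed, and 12 of the 24 liver genes named by rule on average or at ZT18 lost their call. With the replicate number as a block 127 differed, and 18 of the 24 lost their call. The 10 largest rises by the rule for named genes were Cyp4a14, Kctd12, Amigo2, Cyp4a31, Rdh9, Irak3, H2-Q1, Cyp4a10, Serpina3f and Vnn1, from 2.95 down to 1.75. The 10 largest falls were Hcn3, Thrsp, Nat8, Pklr, Fasn, mt-Nd4l, Angptl8, Aqp8, Adam11 and Tff3, from -3.17 to -2.03. Thrsp, a regulator of lipid synthesis, fell from 756 to 119 CPM (log2 difference -3.0, SE 0.58, adjusted p = 0.00739). Pklr, the liver pyruvate kinase, fell from 136 to 22.9 CPM (-2.58, SE 0.47, adjusted p = 0.00578), and Angptl8, an inhibitor of lipoprotein lipase induced by feeding, from 224 to 31.2 CPM (-2.37, SE 0.44, adjusted p = 0.00685). Cyp4a14, Cyp4a31 and Cyp4a10 are near-identical neighbours on chromosome 4, so reads may be split between them and their single values are uncertain. Fasn lies on chromosome 11 from 120696672 to 120715373 on the minus strand of GRCm38, and Srebf1 on the same chromosome from 60089915 to 60113407.

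Without the 11 numbers the fatty acid and cholesterol lists lay further from 0, and the cell cycle and macrophage lists were not called. The 11 were picked by their liver cell cycle mean, so the loss of that rise follows from the choice. Averages without the 11 numbers lack ZT22, where no iKO library is left. At ZT22 the oxidation list was lower in iKO, as given below, so part of its larger mean may come from the times averaged. Of the 35 oxidation genes 28 rose and none fell (mean 1.23, adjusted p = 3.07e-33, adjusted p = 0.0686 with an estimated correlation; 31 adjusted over the list alone). Cpt1a, which admits fatty acids to mitochondria, rose by 1.17 (SE 0.12) and Angptl4, an inhibitor of lipoprotein lipase induced by fasting, by 2.13 (SE 0.17). Of 23 cholesterol synthesis genes 14 fell (adjusted p = 5.23e-15, and 0.255 with an estimated correlation; 17 adjusted over the list alone), including Insig1 (-1.60, SE 0.17) and Fdps (-2.43, SE 0.40). Fatty acid synthesis had 11 genes lower and 2 higher (adjusted p = 1.19e-05, and 0.312 estimated; 13 and 3 adjusted over the list alone), with Fasn at -2.96 (SE 0.38) and Srebf1 at -2.34 (SE 0.19). Fatty acid uptake had 11 higher and 1 lower (adjusted p = 1.66e-07, and 0.131 estimated; 14 and 2 adjusted over the list alone). Of 24 insulin-responsive and fasting-responsive genes 8 rose and 2 fell (adjusted p = 0.000252; 11 and 2 adjusted over the list alone), the 1 list of 42 that was also called with an estimated correlation (adjusted p = 0.0408). Srebf1 was among its falls. The cell cycle mean was -0.19 and the macrophage mean -0.14, neither called. The interferon-stimulated list turned lower, with its values given under Other observations. In all, 1233 genes differed, 562 higher and 671 lower, and 274 of the 438 were called again with the same sign. Kctd12 (0.44, adjusted p = 0.166), Rdh9, Irak3, H2-Q1, Serpina3f, mt-Nd4l and Tff3 were not.

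**Figure D1:**
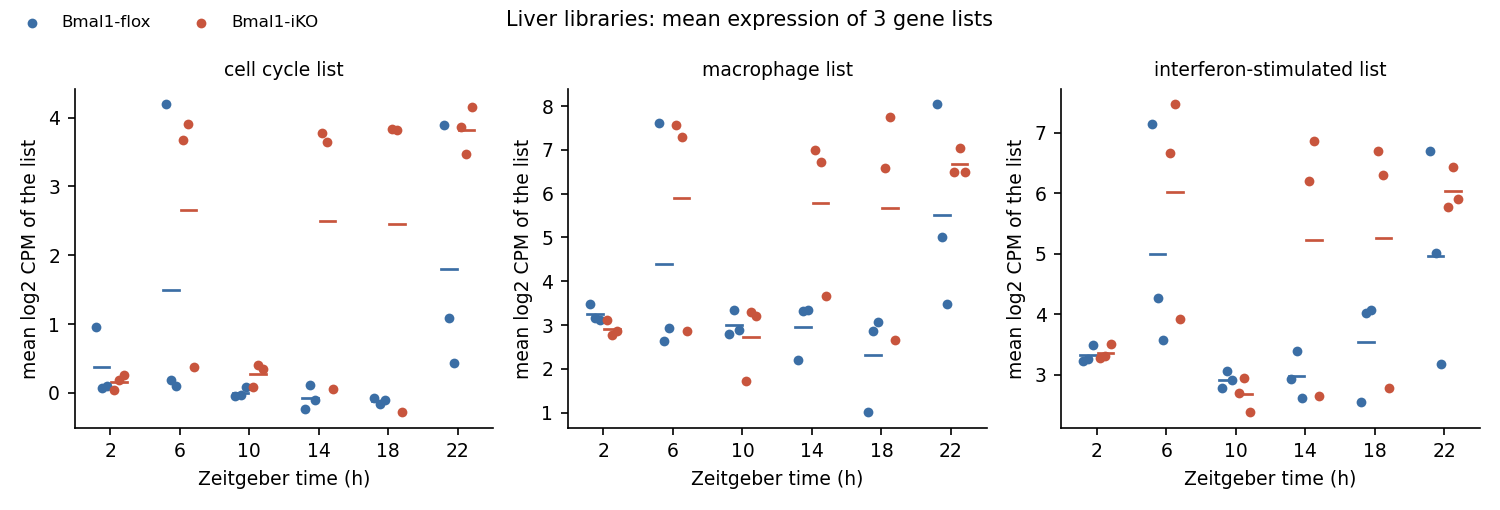
Mean log2 CPM (vertical axis) over the cell cycle, macrophage and interferon-stimulated lists in each of the 36 liver libraries against zeitgeber time in hours, 1 point per library and a bar for the mean of each group of 3. The 11 libraries that stood apart lie at 3.47 to 4.19 for the cell cycle list and the other 25 at -0.29 to 1.09.

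**Figure D2:**
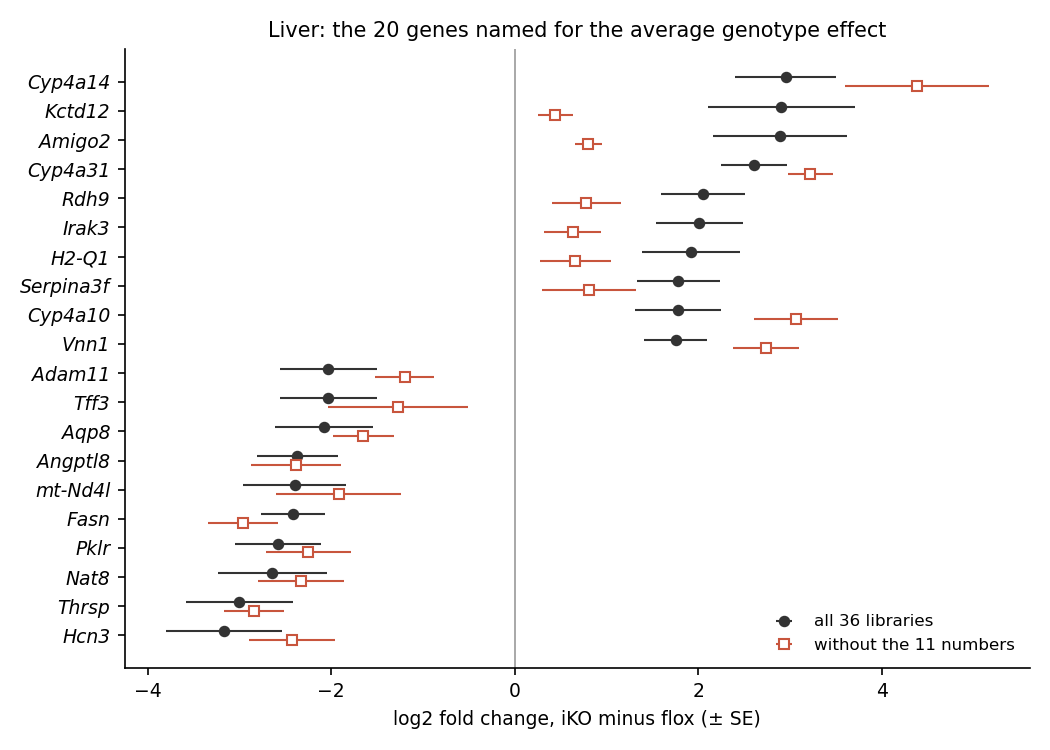
Log2 fold change, iKO minus flox, averaged over the day (horizontal axis, with SE as bars) of the 20 liver genes named by rule, with all 36 libraries (filled) and without the 11 numbers (open). Fasn lies at -2.42 and -2.96, and Kctd12 at 2.90 and 0.44.

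Fatty acid oxidation genes were higher in iKO liver at ZT2 (mean 1.27, adjusted p = 9.8e-16) and ZT10 (mean 1.20, adjusted p = 2.17e-16), the times that hold none of the 11 libraries, with 3 libraries per genotype. With an estimated correlation the adjusted p was 0.755 at each. Fatty acid synthesis was lower at ZT18 (mean -1.62, adjusted p = 2.3e-07, and 0.755 estimated), as was cholesterol synthesis (mean -1.54, adjusted p = 7.27e-09, and 0.873 estimated). Fatty acid oxidation was lower in iKO at ZT22 (mean -0.60, adjusted p = 0.000353, and 0.873 estimated), where all 3 iKO libraries are among the 11. Cell cycle genes were higher at ZT14 (mean 2.85, adjusted p = 4.09e-08), ZT18 (3.26, adjusted p = 3.04e-09) and ZT22 (1.37, adjusted p = 6.3e-22), times at which 2, 2 and 3 of the iKO libraries stood apart. Of 252 pairs of list and time in liver, 90 were called and none with an estimated correlation, and 62 were called without the 11 numbers.

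Single liver genes were called at ZT18 alone, where 6 of 16582 differed by edgeR and 1389 by DESeq2. Tkfc, the triokinase that handles fructose, fell by 2.67 (SE 0.51, adjusted p = 0.0485) and Ero1b, an oxidase of the endoplasmic reticulum, by 1.57 (SE 0.30), while Unc93a2 rose by 3.19 (SE 0.61). No gene was called in a fit of the ZT18 libraries alone, without the 2 Xist numbers, or without flox ZT18 2, flox ZT18 3, iKO ZT18 1 or iKO ZT18 2, and 1893 were called without iKO ZT18 3. In each of the 6 genes the 3 flox and 3 iKO libraries did not overlap. Chance gives this for 10% of genes, and since the 6 were picked by their difference at ZT18, it adds no support. At ZT2, ZT6, ZT10, ZT14 and ZT22 edgeR called 0 genes, with 707, 708, 904, 3293 and 570 at an unadjusted p under 0.05, and DESeq2 called 24, 4, 24, 512 and 13. Without the 11 numbers edgeR called 28 genes at ZT2, 2 at ZT6, 65 at ZT10, 121 at ZT14 and 52 at ZT18. At ZT6, ZT14 and ZT18 these fits hold 1 iKO library, which is assumed to vary like the libraries of the other groups. The genotype by time interaction was called for 0 genes (lowest adjusted p = 0.224, 1069 at an unadjusted p under 0.05, 43 called by DESeq2; 0 without the 11 numbers, with 1449 at an unadjusted p under 0.05), so no gene's difference was shown to vary over the day. In simulated data the test at ZT18 recovered 1% of 2-fold and 36% of 4-fold changes in liver, and the interaction test 0% and 3%.

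Daily rhythms in liver were called for 128 genes in flox and 14 in iKO by a 24 h cosine fit. The flox genes with the smallest p included Arntl (amplitude 1.58, SE 0.17, peak at 18 h), the clock repressors Nr1d2, Cry1 and Per3, the clock output gene Dbp, and Upp2, a uridine phosphorylase with an amplitude of 1.45 in flox and 0.32 in iKO. Of the 128, 35 peaked between 0 and 6 h, 12 between 6 and 12 h, 65 between 12 and 18 h and 16 between 18 and 24 h. The 14 of iKO had 6, 7, 0 and 1 in these bins. With time as a factor with 6 levels, differences over time were called for 682 genes in flox and 1916 in iKO. The order of the 2 genotypes therefore depends on the model. In iKO the libraries that stood apart lie at ZT6, ZT14, ZT18 and ZT22 and none at ZT2 or ZT10. The test of time as a factor does not separate them from time of day. Leaving out 1 library gave 62 (without flox ZT18 2) to 202 genes (without flox ZT6 1) in flox and 4 (without iKO ZT6 3 or iKO ZT18 1) to 48 (without iKO ZT6 2) in iKO. The 7 genes rhythmic in both had a median peak difference of -1.46 h (quartiles -1.71 and 0.124 h), which turned to 0.942 h without iKO ZT18 1. A change of rhythm itself was called for 0 genes by edgeR (lowest adjusted p = 0.301, 794 at an unadjusted p under 0.05, 3 called by DESeq2), so a loss of rhythm in iKO was not shown for any gene by the main test. With the 11 numbers left out, 1395 genes were rhythmic in flox and 149 in iKO, and the change was again called for 0 (2132 at an unadjusted p under 0.05). This drops 9 iKO and 2 flox libraries, among them all iKO libraries of ZT22. The counts of rhythmic genes therefore do not compare the genotypes with equal power. Simulated changes of rhythm of 2-fold and 4-fold were recovered for 31% and 99% of genes.

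In kidney the cell cycle list was lower in iKO and the interferon list higher. Of 30 cell cycle genes 2 fell, Cdc20, an activator of the anaphase-promoting complex (-0.95, SE 0.16, adjusted p = 0.00792), and the cyclin Ccnb2 (-1.25, SE 0.26, adjusted p = 0.0349). The list was called with a preset correlation (mean -0.52, adjusted p = 2.85e-19; 16 lower adjusted over the list alone) and with an estimated one (adjusted p = 0.0384). Interferon-stimulated genes were higher as a list (mean 0.95, adjusted p = 1.05e-17, and 0.700 estimated), with 0 of 34 called and 31 higher adjusted over the list alone, and the iKO group holds 9 of the 11 numbers with high interferon genes. Mitochondrially encoded genes (adjusted p = 3.36e-07, 12 of 13 lower adjusted over the list alone), cholesterol synthesis (9.99e-06) and fatty acid synthesis (0.0181) were lower, each with adjusted p = 0.700 with an estimated correlation. Ribosomal proteins (6.41e-05), fatty acid oxidation (0.000764) and immediate early genes (0.0128) were higher, and proximal tubule transporters (0.0148) and extracellular matrix genes (0.0434) lower, each with adjusted p = 0.926 estimated. The 10 lists called came from 39 tested.

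Single kidney genes called on average numbered 29 of 17630, 13 higher and 16 lower, and DESeq2 called 203. Leaving out 1 library gave from 10 (without flox ZT6 3) to 125 genes (without flox ZT6 1), and 7 of the 18 genes named by rule stayed called in all 36 such fits. Without the 3 numbers whose clock genes fitted another time 6 differed, and 15 of the 18 lost their call. With the replicate number as a block 5 differed, and 15 of the 18 lost their call. The largest rises were Loxl4, a lysyl oxidase (2.01, SE 0.37, adjusted p = 0.0191), Bhmt, which methylates homocysteine (1.90, SE 0.37, adjusted p = 0.0293), and Npas2, a partner of Arntl in the clock (1.49, SE 0.28, adjusted p = 0.0251), whose mean was 9.98 CPM in flox and 21.7 CPM in iKO. Kcnip2, Aadat, Cdhr2, Arrdc4, Pygl and Slc35f2 rose by 0.95 down to 0.32. The immunoglobulin gene Igha fell by 2.53 (SE 0.54), Spns3 by 1.62, Mgp, an inhibitor of calcification, by 0.84, Gdf10 by 0.82 (SE 0.13, adjusted p = 0.00475), Cxcl14 by 0.81, and Loxl1, Fads1 and Ccdc50 by 0.59, 0.59 and 0.25. Npas2 lies on chromosome 1 from 39232812 to 39402317.

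Without the 11 numbers genes of fatty acid oxidation and uptake were higher in iKO kidney, and the fatty acid synthesis list was not called (2 of 26 genes lower and 1 higher, 3 and 1 adjusted over the list alone, mean -0.01, median 0.06, test direction up, adjusted p = 0.899). Of 35 oxidation and ketone genes 7 rose (mean 0.66, adjusted p = 3.95e-36, and 0.0203 with an estimated correlation; 27 adjusted over the list alone). Pdk4, a kinase that spares glucose from oxidation, rose by 2.70 (SE 0.26, adjusted p = 0.000149). Fatty acid uptake had 2 genes higher (adjusted p = 6.89e-08, and 0.0203 estimated; 9 adjusted over the list alone), the lipases Lipe and Pnpla2. The cell cycle list stayed lower (adjusted p = 1.51e-20, and 0.0425 estimated; 4 called and 18 adjusted over the list alone), with Top2a at -1.47 and Mki67 at -1.32. The interferon list turned lower (mean -0.30, adjusted p = 0.00122, and 0.671 estimated). In all 80 genes differed, 43 higher and 37 lower, and 12 of the 29 were called again. Loxl4 (adjusted p = 0.193), Kcnip2, Aadat, Igha and Fads1 were among those not called, while Npas2 was (1.87, SE 0.34, adjusted p = 0.0217).

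At single times kidney had 2 calls, both at ZT22, the pseudogene Ndufab1-ps (1.28) and the predicted gene Gm10819 (-1.69), named because they are the whole count. DESeq2 called 67 there, and edgeR called 0 without flox ZT22 3, without iKO ZT22 3, without the 2 Xist numbers, without the 3 numbers with shifted clock genes and in a fit of that time alone. At ZT2, ZT6, ZT10, ZT14 and ZT18 edgeR called 0 genes, with 1141, 1096, 513, 1236 and 2495 at an unadjusted p under 0.05, and DESeq2 called 0, 1, 1, 18 and 133. The interaction was called for 0 (lowest adjusted p = 0.271, 1373 at an unadjusted p under 0.05, 55 by DESeq2). Leaving out iKO ZT18 3 gave 479 genes at ZT18, and leaving out iKO ZT14 3 gave 27 at ZT14. In simulated kidney data the ZT18 test recovered 47% of 2-fold and 97% of 4-fold changes. Fatty acid oxidation was higher as a list at ZT2 (mean 0.68, adjusted p = 7.82e-09) and ZT10 (0.43, adjusted p = 3.21e-06), the times without any of the 11 numbers. Of the kidney pairs of list and time 61 were called, and 0 with an estimated correlation. Leaving out the 11 numbers gave 60 such pairs, 1 gene for the interaction and 4 genes at ZT14, where the lone iKO library is assumed to vary like those of other groups.

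Kidney rhythms were called for 894 genes in flox and 744 in iKO, and 361 were shared. Leaving out 1 library gave 345 (without flox ZT2 3) to 1206 genes (without iKO ZT2 1) in flox and 157 (without iKO ZT10 1) to 1583 (without iKO ZT2 1) in iKO. Per3 had the smallest p among them with adjusted p = 4.16e-05 in flox and 1.1e-05 in iKO. The median peak difference of the shared genes, iKO minus flox, was -1.58 h (quartiles -2.32 and -0.768 h). Flox peaks fell 389, 118, 317 and 70 to the bins starting at 0, 6, 12 and 18 h, and iKO peaks 150, 257, 104 and 233. With time as a factor with 6 levels, differences over time were called for 2185 genes in flox and 7058 in iKO, the opposite order. The iKO libraries of the 11 numbers include none from ZT2 or ZT10, so this test does not separate them from time of day. Without the 2 Xist numbers 167 genes were rhythmic in iKO, and without the 3 numbers whose clock genes fitted another time 144. With the 11 numbers left out, 1695 genes were rhythmic in flox and 13 in iKO, with 8 shared and a median of -0.559 h. This drops 9 iKO and 2 flox libraries, among them all iKO libraries of ZT22. The 2 counts therefore do not compare the genotypes with equal power. A change of rhythm was called for 0 genes (lowest adjusted p = 1, 378 at an unadjusted p under 0.05, 0 by DESeq2). Simulated changes of 2-fold and 4-fold, each a rhythm in iKO against none in flox, were recovered for 87% and 100%. Smaller changes were not simulated, so the 0 calls do not show that rhythms were unchanged.

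**Figure D3:**
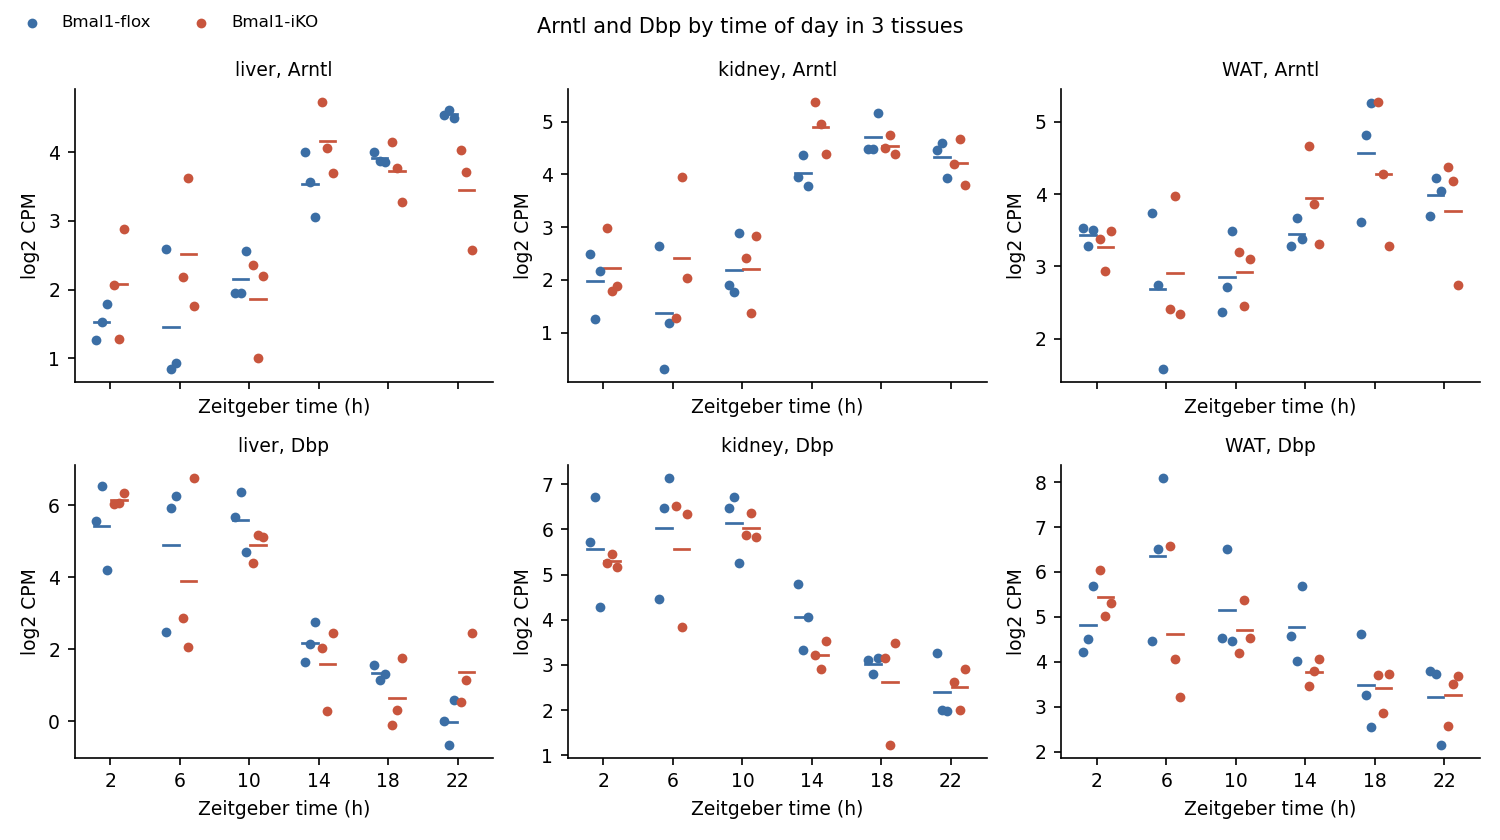
Log2 CPM (vertical axis) of the clock genes Arntl and Dbp in liver, kidney and WAT against zeitgeber time in hours, 1 point per library and a bar for the mean of each group of 3 in flox and iKO. Liver Arntl had its fitted peak at 18 h in flox and 17.29 h in iKO.

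Some core clock genes were called rhythmic in liver and kidney of each genotype. Of 22, 8 were called rhythmic in flox liver and 4 in iKO liver, 14 and 12 in kidney, and 0 and 0 in WAT. Liver Arntl had a fitted peak at 18 h (SE 0.40) in flox and 17.29 h (SE 0.94) in iKO, where its rhythm was not called (adjusted p = 0.129), and kidney Arntl at 18.2 h (SE 0.39) and 17.59 h (SE 0.69). Fitted amplitudes were smaller in iKO for 18 of 22 genes in liver (medians 1.41 and 0.82), 16 in kidney (1.01 and 0.68) and 16 in WAT (0.54 and 0.41). In a permutation test that exchanged genotypes within each time, 0 of 66 pairs of gene and tissue had a called change of peak or amplitude. The lowest adjusted p for peak and amplitude were 0.617 and 0.472 in liver, 0.317 and 0.517 in kidney and 0.854 and 0.982 in WAT. In 3 iKO numbers the clock genes of all 3 tissues fitted another time best, with liver, kidney and WAT offsets of 8.8, 9.4 and 10.1 h for ZT6 2, 4.0, 4.0 and 4.1 h for ZT14 2, and -5.5, -5.3 and -6.3 h for ZT22 3. All 3 are among the 11 numbers that stood apart in liver. Without these 3 numbers, an alternative chosen after the data were seen, 158 genes differed on average in liver and 6 in kidney. In the same fits the amplitude was smaller in iKO for 14 of 22 clock genes in liver, 10 in kidney and 15 in WAT, with medians of 0.97, 0.80 and 0.59 in iKO.

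In WAT no single gene differed between the genotypes by the main test, and many libraries held RNA of genes known from other tissues. Among 36 WAT libraries 13, of which 6 were flox and 7 iKO, had means over epididymis and testis markers above 6 log2 CPM, and 8, of which 3 were flox and 5 iKO, had skeletal muscle or adrenal markers above that level. In flox ZT10 1 the seminal vesicle genes Svs2, Svs5 and Svs4 held 16.8, 14.9 and 11.7% of all counts, and in flox ZT22 3 mitochondrially encoded genes held 46.8%. Over 21402 genes edgeR called 0 on average, with 805 at an unadjusted p under 0.05, and DESeq2 called 25. Simulated changes of 2-fold and 4-fold were recovered for 34% and 97% of genes.

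As lists, interferon-stimulated genes (mean 0.66, adjusted p = 8.38e-10), hepatocyte markers (1.26, adjusted p = 1.23e-07), fatty acid oxidation (0.42, adjusted p = 1.61e-05) and B cell markers (1.14, adjusted p = 0.000157) were higher in iKO WAT. Antigen presentation (0.000709), ribosomal proteins (0.0112), macrophage (0.0258), endothelial (0.0264) and skeletal muscle markers (0.0474) were also higher. Mesothelial markers (mean -0.52, adjusted p = 0.00133), NRF2-responsive genes (0.00478), cholesterol synthesis (0.00801), the cell cycle (0.0358), fatty acid synthesis (0.0383) and glycolysis (0.0474) were lower. Of the 15 calls among 34 lists none held with an estimated correlation, where adjusted p ran from 0.197 for NRF2-responsive genes to 0.907. No member was called singly. When the 11 numbers were left out the means were -0.24 for interferon-stimulated genes, -0.54 for hepatocyte markers, -0.72 for B cell markers and 0.02 for fatty acid oxidation, none of them called. Endothelial (-0.44, adjusted p = 0.0381) and skeletal muscle markers (-3.85, adjusted p = 0.000607) were then lower, each with adjusted p = 0.882 with an estimated correlation. Adjusted over the list alone, 7 of 15 B cell markers, 2 hepatocyte markers, 2 oxidation genes, 1 endothelial and 1 macrophage marker were higher. Vnn1 stood at 2.81 (SE 0.72) and Pdk4 at 1.99 (SE 0.54). At single times skeletal muscle markers differed by 9.96 at ZT14 (adjusted p = 1.05e-13, and 0.761 with an estimated correlation), where iKO ZT14 1 and 2 are among the 8 libraries named above, and B cell markers by 4.91 at ZT6 (adjusted p = 2.4e-28, and 0.0699 estimated), where iKO ZT6 1 and 2 had means of 5.0 and 3.61 log2 CPM.

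At each single time edgeR called 0 WAT genes, with 469, 697, 1241, 757, 1193 and 221 at an unadjusted p under 0.05 from ZT2 to ZT22, and DESeq2 called 36, 37, 84, 71, 54 and 31. Rhythms were called for 0 genes in flox (2074 at an unadjusted p under 0.05, 116 by DESeq2) and 0 in iKO (809, and 0 by DESeq2). The interaction and the change of rhythm were called for 0 genes, with 564 and 674 at an unadjusted p under 0.05 and 0 each by DESeq2. Without the 11 numbers the average called 0 (1078 at an unadjusted p under 0.05). Simulated 2-fold and 4-fold rhythms in flox were recovered for 18% and 91% of genes, changes of rhythm for 2% and 52%, differences at ZT18 for 0% and 4% and interactions for 0% and 1%.

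**Figure D4:**
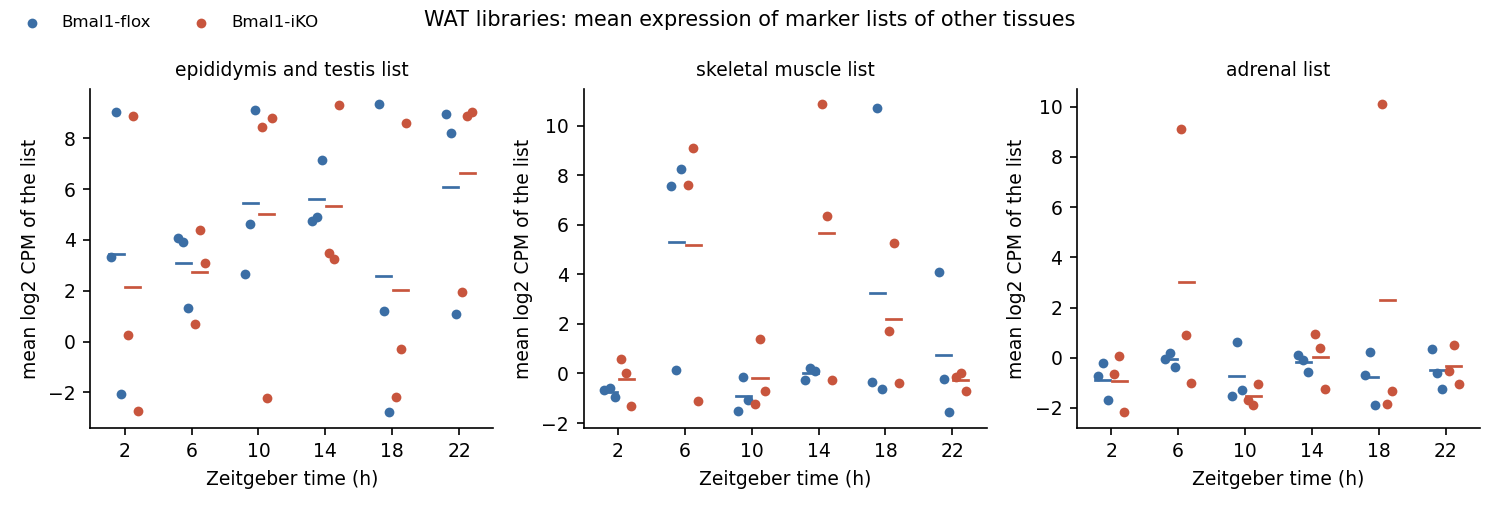
Mean log2 CPM (vertical axis) over the epididymis and testis, skeletal muscle and adrenal lists in each of the 36 WAT libraries against zeitgeber time in hours, 1 point per library and a bar for the mean of each group of 3. The epididymis and testis list lies above 6 in 13 libraries of both genotypes.

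The genotype difference was then compared between tissues, in 1 model over the libraries of all 3 tissues. Between liver and kidney 90 of 22789 genes differed in their response, 56 with the larger value in liver, and DESeq2 called 429. The Thrsp effect was -3.0 (SE 0.58) in liver and 0.54 (SE 0.35) in kidney, a difference of -3.55 (adjusted p = 0.0166). The insulin-regulated glucose transporter Slc2a4 differed by -2.67, the water channel Aqp8 by -3.81, Ptges by -2.46 and Bhmt by -2.44. Differences the other way were Miox (3.35), the replication genes Top2a (3.07) and Uhrf1 (2.52), the mitotic kinase Cdk1 (2.43) and Amigo2 (2.47). Leaving out the 11 numbers gave 15 genes, 5 of them called in both fits. None of the 10 genes named here was among them (adjusted p from 0.0614), with Miox at 1.13, Top2a at 0.07, Uhrf1 at 0.61, Amigo2 at 0.93 and Cdk1 at 1.05. The 11 were picked by their liver cell cycle mean, so a smaller liver effect of cell cycle genes such as Top2a follows from that choice.

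Between liver and WAT 135 genes differed (709 by DESeq2), 68 with the larger value in liver, led by Cdhr2 (4.10), Cyp4a14 (3.91), Slc12a2, Grhl1 and Top2a, and on the other side by C4a (-3.39), Efhd1, Apoa1 (-3.09), Apoc4 and Klhdc8a. Leaving out the 11 numbers gave 82, 14 of them called in both fits, among them Cyp4a14 (5.95, adjusted p = 0.00819). The remaining 9 genes named here were not called, and Cdhr2 stood at -0.97, Top2a at -1.25, Apoa1 at -0.67 and C4a at -1.69. Between kidney and WAT 3 genes differed (58 by DESeq2), Cbr1 (1.76), Gm12781 (-2.71) and the immunoglobulin gene Igkv17-121 (-6.88). A difference in the change of rhythm was called for 1 gene, Spink4, against kidney and WAT alike, and for 0 between kidney and WAT (686 at an unadjusted p under 0.05, 3 called by DESeq2). Spink4 stood at 2.28 log2 CPM in the liver library iKO ZT2 2 and at most -1.83 in the other 35 liver libraries. Leaving out all libraries numbered 2 left 0 average differences for each pair of tissues.

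**Figure D5:**
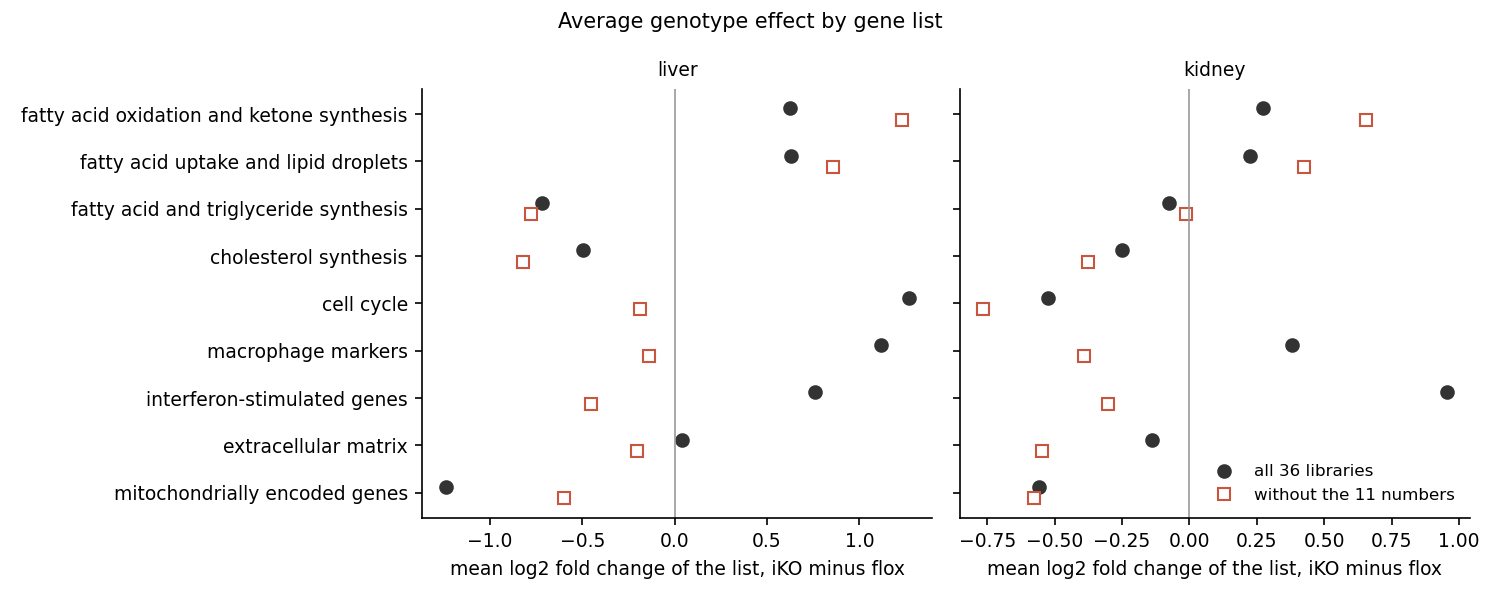
Mean log2 fold change, iKO minus flox (horizontal axis), of 9 gene lists in liver and kidney, with all 36 libraries (filled) and without the 11 numbers (open), drawn without error bars. The liver fatty acid oxidation list lies at 0.62 and 1.23 and the liver cell cycle list at 1.27 and -0.19. Averages without the 11 numbers lack ZT22, and the 11 were picked by their liver cell cycle mean.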

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

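The differences between tissues in this part were planned, the test on genes of newborn organs was written before its values were seen, and the tests on kidney interferon genes and on T cell genes were chosen after the result was seen.

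The genotype effect differed between liver and kidney for 90 genes, between liver and WAT for 135 and between kidney and WAT for 3, each by a test of the difference of the effects in 1 model. Other splits of the samples did not exclude chance for the 135 (3 of 21, highest other 1349) or for the 3 (3 of 21, highest other 165), and leaving out all libraries numbered 2 left 0 for each pair. For the 90 the real split alone gave as many (1 of 21), the smallest share these splits allow. Liver minus kidney, the log2 differences were 3.35 for Miox, which breaks down inositol, 3.07 for Top2a, 2.52 for Uhrf1, 2.47 for Amigo2 and 2.43 for Cdk1. They were -3.81 for Aqp8, -3.55 for Thrsp, -2.67 for Slc2a4, -2.46 for Ptges and -2.44 for Bhmt. None of these 10 was called without the 11 numbers, an alternative chosen after the data were seen, and Miox stood at 1.13, Top2a at 0.07, Uhrf1 at 0.61, Amigo2 at 0.93 and Cdk1 at 1.05. Since the 11 were picked by their liver cell cycle mean, a smaller liver effect of cell cycle genes such as Top2a follows from that choice. Liver minus WAT, they were 4.10 for Cdhr2, 3.91 for Cyp4a14, 2.67 for Slc12a2, 2.64 for Grhl1 and 2.51 for Top2a. They were -3.39 for C4a, -3.18 for Efhd1, -3.09 for Apoa1, -2.84 for Apoc4 and -2.84 for Klhdc8a. Of these 10 only Cyp4a14 (5.95) was called without the 11 numbers, and Cdhr2 (-0.97) and Top2a (-1.25) changed sign. Kidney minus WAT, Cbr1 stood at 1.76, and at 0.67 (not called) without the 11 numbers. The change of rhythm differed for 1 gene between liver and kidney and for 1 between liver and WAT, Spink4 in both cases, which rests on the liver library iKO ZT2 2.

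In liver, 11 libraries, 9 iKO and 2 flox, had cell cycle means of 3.47 to 4.19 log2 CPM against at most 1.09 in the other 25, with H19 at 1.26 to 10.13 against at most 1.11 and B cell means of 0.99 to 3.99 against at most 0.80. For the interferon genes the tables argue against a library batch of the liver alone. Of the 11 kidney libraries with the same numbers, 9 had an interferon mean above the highest of the other 25. The cell cycle and macrophage genes were not tested in this way, so for them such a batch stays open. RNA of T cells mixed into the liver samples stays open and may account for part, since 9 of the 11, neither all 11 nor under 6, had a T cell mean above the other 25, with Gzma and Thy1, the most abundant of 18 list genes that liver expresses, at medians of 4.88 and 3.66 log2 CPM. Animals younger than the others stay open too, since 5 of the 11 kidney libraries, between the bounds of 3 and 9 set in advance, had a mean over 8 newborn genes above the other 25. The same mean was above the other 25 in 10 of the 11 in liver and in 2 of the 11 in WAT, tissues for which no bounds were set. Gene by gene, Dlk1 and Peg3 were above the other 25 in 6 of the 11 kidney libraries. Mest was in 5, Igf2bp3 in 4, Plagl1 in 3, and H19, Igf2 and Gpc3 in 0. Genotype as the cause was not tested, and 2 flox libraries share the pattern while 9 of the 18 iKO libraries lack it.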

How the results depend on the processing

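The fits without libraries that stood apart were chosen after the data were seen, and the other alternatives before the data were examined. Apart from fits with 1 library left out, 260 counts and medians stayed within 1.5 times the reported count, or within 1 SD over draws for a median peak difference (0.61 h in liver, 0.777 h in kidney), and 117 did not. With a library left out 1387 did and 215 did not. None of the 24 liver and 18 kidney genes named by rule for their own call changed sign in these fits (signs of genes named as list members were not counted), where 184 calls of single genes held and 110 were lost, and 1119 held and 393 were lost with a library left out. Of the genes named for a difference between tissues, Cdhr2 and Top2a changed sign between liver and WAT without the 11 numbers (-0.97 and -1.25). Clock gene peaks and amplitudes kept 0 calls in every fit run. Size factors of DESeq2 in place of TMM moved the median liver peak difference from -1.46 to -0.832 h and no count. At these depths and spreads simulated 2-fold average effects were recovered for 84% of genes in liver, 100% in kidney and 34% in WAT. Where no reason is given, the cause was not tested.

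DESeq2 called more genes than edgeR in most results. In liver it called 1609 on average, 24, 4, 24, 512, 1389 and 13 from ZT2 to ZT22, 43 for the interaction, 476 rhythmic in flox, 213 in iKO and 3 with a change of rhythm. In kidney it called 203 on average, 1, 1, 18, 133 and 67 from ZT6 to ZT22, 55 for the interaction, 1722 rhythmic in flox and 1579 in iKO. In WAT it called 25 on average, 36, 37, 84, 71, 54 and 31 from ZT2 to ZT22 and 116 rhythmic in flox. Between tissues it called 429, 709 and 58 average differences for liver and kidney, liver and WAT, and kidney and WAT, and 2, 0 and 3 changes of rhythm.

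With no filter on low counts, which adds genes to the adjustment, liver had 218 genes on average, 77 rhythmic in flox, a median peak difference of -0.485 h and 23 lists called. Kidney had 473 and 417 rhythmic genes and WAT 10 and 1. Average differences between tissues numbered 41 for liver and kidney and 32 for liver and WAT, and changes of rhythm 3, 12 and 7 for the 3 pairs of tissues, with the dispersion trend of the filtered fit.

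Taking the replicate number as a block left 127 average genes in liver, 0 at ZT18, 8 rhythmic in iKO and a median peak difference of 0.724 h, 5 average genes and 5 at ZT22 in kidney, 31 average differences between liver and WAT, 0 between kidney and WAT and 0 changes of rhythm for liver against kidney and against WAT. Of the named genes 18 of 24 in liver and 15 of 18 in kidney lost their call under the block. It moved no other count by over 1.5 times. The numbers do not pair flox with iKO. Deviations of flox and iKO libraries with the same number correlated above 0.1 in 11, 9 and 9 of 18 pairs in liver, kidney and WAT, and a library correlated best with its own number in 7, 6 and 8 of 18. Across tissues, libraries of the same genotype, time and number correlated above 0.1 in 23, 11 and 14 of 36 pairs and best with their own number in 23, 17 and 27 of 36 for liver and kidney, liver and WAT, and kidney and WAT. This is a hint that a number is shared between tissues. The clock offsets of 3 iKO numbers differed by at most 1.3 h between tissues. These numbers were picked for an offset of at least 3.5 h in each tissue, so they add little support. The main comparisons between tissues do not model a shared number. Their block was genotype, time and number across tissues, which does model it and left the 31 and 0 average differences from WAT given above.

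Fits of single times gave 5 genes at ZT2, 297 at ZT10 and 0 at ZT18 in liver, and 5 at ZT10 and 0 at ZT22 in kidney. Fits of single genotypes, with fewer libraries, gave 73 rhythmic genes in flox and 0 in iKO liver, 1627 and 149 in kidney and 3 in flox WAT. Time as a factor with 6 levels gave 682 and 1916 in liver, 2185 and 7058 in kidney and 11 in flox WAT. In liver and kidney this turned the order of flox and iKO. In iKO the libraries that stood apart include none from ZT2 or ZT10, so time as a factor does not separate them from time of day. A peak-to-trough ratio of at least 1.5 kept 128 and 14 in liver and 782 and 656 in kidney. With an estimated correlation 0 of the average lists were called in liver, 1 in kidney and 0 in WAT, and 0 lists at single times in each tissue.

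Without the 11 numbers with high cell cycle genes liver had 1233 genes on average, 28, 2, 65, 121 and 52 from ZT2 to ZT18, 1395 and 149 rhythmic and a median peak difference of -0.708 h. Kidney had 80 on average, 4 at ZT14, 1 for the interaction, 1695 and 13 rhythmic, a median of -0.559 h and 19 lists, and WAT 1 gene at ZT6. At ZT6, ZT14 and ZT18 these fits have 1 iKO library, assumed to vary like the other groups. They lack iKO at ZT22, so their counts of rhythmic genes do not compare the genotypes with equal power. Between tissues 15, 82 and 1 average differences were called, with 0 changes of rhythm for liver and kidney and 6 for liver and WAT. Without the 2 numbers with Xist and no Y-linked genes liver had 201 on average, 0 at ZT18, 2 rhythmic in iKO and a median of 0.321 h, and kidney 1 at ZT18, 0 at ZT22 and 167 rhythmic in iKO. Without the 3 numbers with shifted clock genes liver had 158 on average, 3 at ZT18, 25 rhythmic in iKO and a median of -0.425 h, kidney 6 on average, 0 at ZT22 and 144 rhythmic in iKO, and WAT 9 lists. Without the 8 WAT libraries with muscle or adrenal genes WAT had 9 lists.

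Leaving out 1 library moved the liver average from 438 to 217 without iKO ZT10 2, 220 and 231 without flox ZT6 2 and 3, 253 and 268 without iKO ZT18 2 and 1, 260 without flox ZT22 2 or 3, 268 without flox ZT10 1, 280 and 285 without iKO ZT2 3 and 1 and 287 without flox ZT18 3. It was 1152 without iKO ZT14 3, 2011 without iKO ZT6 3, 2068 without iKO ZT18 3, 2511 without flox ZT22 1 and 3259 without flox ZT6 1, and between 216 and 438 of the 438 were called again. The kidney average moved from 29 to 10 without flox ZT6 3, 11 without flox ZT10 1 or flox ZT18 1, 14 without iKO ZT2 1, 15 without flox ZT10 3, iKO ZT10 2 or iKO ZT22 3, 18 without flox ZT2 3 or flox ZT22 3, and 19 without flox ZT6 2, iKO ZT14 1 or iKO ZT6 2. It was 58 without flox ZT22 1, 59 without iKO ZT6 3, 60 without iKO ZT14 3, above 60 also without iKO ZT18 3, and 125 without flox ZT6 1. Of the named genes, Kctd12, H2-Q1, Adam11, Tff3, Cyp4a10 and Aqp8 in liver lost their call in 31, 29, 23, 22, 20 and 17 of 36 such fits, and Igha, Slc35f2, Loxl1 and Kcnip2 in kidney in 28, 25, 23 and 19. Loxl4 lost it without flox ZT6 3 alone (adjusted p = 0.0503) and mt-Nd4l without flox ZT6 2 alone (adjusted p = 0.0575), by edgeR.

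In liver at ZT18 the 6 calls ended without flox ZT18 2 or 3 or iKO ZT18 1 or 2, were 2 or 3 in 24 further fits, and rose to 11 without iKO ZT6 3, 19 without iKO ZT14 3, 37 without flox ZT22 2, 249 without flox ZT22 1, 489 without flox ZT6 1 and 1893 without iKO ZT18 3. The 0 calls elsewhere in liver rose to at most 1 at ZT2 (iKO ZT2 2 or 3), 2 at ZT6 (flox ZT6 1), 2 at ZT14 (flox ZT6 1), 1 at ZT22 (flox ZT22 2) and 2 for the interaction (flox ZT22 2 or iKO ZT2 3). Liver rhythmic genes ran from 62 (flox ZT18 2) to 202 (flox ZT6 1) in flox and from 4 (iKO ZT6 3 or iKO ZT18 1) to 48 (iKO ZT6 2) in iKO, and the median peak difference from -1.62 h (flox ZT2 2) to 0.942 h (iKO ZT18 1). In kidney the 2 calls at ZT22 ended without flox ZT22 3 or iKO ZT22 3 and were 26 without flox ZT22 2, the 0 at ZT6 became 1 (flox ZT6 3 or iKO ZT6 1), at ZT14 27 (iKO ZT14 3), at ZT18 479 (iKO ZT18 3) and for the interaction 2 (flox ZT22 2). Kidney rhythmic genes ran from 345 (flox ZT2 3) to 1206 (iKO ZT2 1) in flox and from 157 (iKO ZT10 1) to 1583 (iKO ZT2 1) in iKO.

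In WAT the lists called ran from 7 (iKO ZT6 2) to 17 (iKO ZT6 3), and the 0 calls became 5 at ZT10 (flox ZT10 3), 2 at ZT22 (flox ZT22 1), 11 rhythmic in flox (flox ZT6 1), 10 in iKO (iKO ZT6 1) and 2 changes of rhythm (iKO ZT18 1). Leaving out all libraries of 1 number gave 0 to 128 average differences between liver and kidney (0 without number 2, 128 without number 3), 0 to 1621 between liver and WAT (0 without number 2, 1621 without number 3) and 0 to 18 between kidney and WAT (0 without number 1 or 2, 18 without number 3). Changes of rhythm ran from 0 (without number 1 or 3) to 1 between liver and kidney and were 0 without any number between liver and WAT.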

Other observations

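The fits without the 11 numbers, and the tests on exchanged libraries, wrong times, reads of other libraries and a change shared by liver and kidney, were chosen after the result was seen, while the test on adjoining tissue was written before its values were seen and the splits were planned. The number of splits for average differences between tissues was lowered to 21, for computing time, after the values of a larger draw had been seen.

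Without the 11 numbers further gene groups differed in iKO liver. Of 26 chaperones of the endoplasmic reticulum 5 fell (adjusted p = 0.000647, and 0.678 with an estimated correlation; 11 lower and 1 higher adjusted over the list alone), including Edem1 (-0.55, SE 0.12), Manf (-0.98, SE 0.22) and Hyou1 (-0.92, SE 0.23). Among 19 NRF2-responsive genes 4 fell and 1 rose (adjusted p = 0.00244, and 0.312 estimated; 6 and 1 adjusted over the list alone), with Tkt (-0.70) and Pgd (-0.99) of the pentose phosphate pathway lower and Aldh3a2, a fatty aldehyde dehydrogenase, higher (0.90). Cholangiocyte markers had 3 of 13 lower (adjusted p = 0.00106, and 0.427 estimated; 4 adjusted over the list alone), Sox9 (-0.95, SE 0.20), Cdh1 (-0.86) and Krt7 (-2.35). Interferon-stimulated genes had 3 of 34 lower (adjusted p = 0.000108, and 0.740 estimated; 6 adjusted over the list alone), among them Oasl1 (-1.26) and Ifih1 (-0.68). These fits hold 16 flox and 9 iKO libraries.

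Kidney without the 11 numbers had 1 of 27 extracellular matrix genes lower, Col6a2 (-0.80, SE 0.15), and 13 lower adjusted over the list alone (list adjusted p = 1.09e-11, and 0.135 estimated). Of 15 genes of gluconeogenesis and glycogen breakdown 2 rose (adjusted p = 2.93e-06, and 0.089 estimated; 5 adjusted over the list alone), Pck1, which commits carbon to glucose synthesis (1.18, SE 0.23), and Slc25a25 (1.19, SE 0.18). Of 23 cholesterol synthesis genes 2 fell (adjusted p = 1.08e-07, and 0.242 estimated; 8 adjusted over the list alone). Slc16a1, a transporter of lactate and ketones, rose by 0.99 (SE 0.15).

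Male-biased liver genes had means of 3.33 to 7.54 log2 CPM in the 11 liver libraries and 6.08 to 8.98 in the other 25, and the female-biased list -0.65 to 3.66 and -1.47 to 3.26. Of the 11, only iKO ZT18 1 and iKO ZT22 3 had Xist above 3 log2 CPM.

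Clock genes of 3 iKO numbers were nearest to another time than the labelled one in all 3 tissues. The offsets of a number differed by at most 1.3 h between tissues. The numbers were picked for an offset of at least 3.5 h in each tissue, all in the same direction. Libraries exchanged within one tissue would not have been picked, so this test cannot decide on such an exchange. Animals labelled with the wrong time stay open as a candidate explanation, since the mean nearest times were 15.4, 18 and 16.3 h for ZT6 2, ZT14 2 and ZT22 3, of which 1 lies at a sampled time and another 1.7 h from any. A shifted clock in these animals was not tested, and the labels give no grouping that could test it. All 3 numbers are among the 11 that stood apart in liver, and ZT22 3 is also 1 of the 2 Xist numbers.

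Epididymis and skeletal muscle genes reached means above 6 log2 CPM in WAT libraries of both genotypes, and adrenal genes in iKO ZT6 1 and iKO ZT18 1. The tables argue against reads of the liver and kidney libraries as the source of the epididymis genes, since the highest epididymis mean of these 72 was -2.22 log2 CPM. Which libraries shared a run with those of WAT is not known here, so reads of other libraries stay open. Tissue next to the fat pad in the sample stays a hypothesis. In all 13 libraries with a list mean above 6 the mean over 14 epididymis genes outside the list, 4.72 to 7.99, exceeded the highest of the 6 libraries with a list mean under 0, at -0.777, which other sources of epididymis RNA would also give and which does not bear on the muscle and adrenal genes. No biological explanation was tested.

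Fatty acid oxidation genes were higher in iKO liver without the 11 numbers, and a change shared by liver and kidney was put forward as a hypothesis after this was seen. In kidney without the same numbers the list was higher at adjusted p = 0.0203 with an estimated correlation, which is consistent with it, while in liver the same test gave 0.0686. The list mean was 1.23 in liver and 0.66 in kidney, with 31 and 27 of 35 genes higher adjusted over the list alone. Food intake was not measured here, and the animals may share their state in both tissues whatever its origin.

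Genotypes were exchanged within each time to see how often other splits of the libraries gave as much. For the liver average 1 of 40 splits, the real one, gave 438 genes and the highest other 0. For the kidney average it was also 1 of 40 (29 genes, highest other 1). With times exchanged within a genotype, the real times alone gave as many rhythmic genes. In liver these were 128 in flox (1 of 40, highest other 3) and 14 in iKO (1 of 40, highest other 1). In kidney they were 894 in flox (1 of 40, highest other 1) and 744 in iKO (1 of 40, highest other 213). Each share is under 0.05, but it is the smallest that 40 splits allow. The real split also puts 9 of the 11 numbers that stood apart in iKO. The shares of the averages therefore do not separate genotype from these numbers. For the median liver peak difference of -1.46 h over 7 genes, 2 of the 83 splits that gave one were as large (highest other -1.5 h), a share under 0.05, but its sign turned without the 2 Xist numbers (0.321 h) and without iKO ZT18 1 (0.942 h). Chance is not excluded for that of kidney (-1.58 h, 7 of 100, highest other 1.92 h). Of the differences between tissues, the real split alone gave as many as the 90 genes between liver and kidney (1 of 21, highest other 0). That share is the smallest these splits allow, and their number was lowered after values had been seen. Leaving out the libraries numbered 2 also left 0 genes, so chance is not held to be excluded for the 90. Chance is also not excluded for the 135 between liver and WAT (3 of 21, highest other 1349) or the 3 between kidney and WAT (3 of 21, highest other 165). Which libraries the highest of these splits put together was not examined. For a change of rhythm 32 of 40 splits gave as many as the 1 gene between liver and kidney (highest other 15), 39 of 40 as many as the 1 between liver and WAT (highest other 174), and between kidney and WAT, with 0 genes, the highest other was 41.

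Chance is not excluded for the number of lists called. In liver 23 of 40 splits had as many average lists as the 15 found (highest other 24) and 6 of 40 as many as 90 lists at single times (highest other 102). In kidney 26 of 40 reached 10 lists (highest other 26) and 22 of 40 reached 61 (highest other 79), and in WAT 13 of 40 reached 15 (highest other 22) and 33 of 40 reached 55 (highest other 93). For results with 0 genes every split reaches the real count, 40 of 40 or 100 of 100, so the share says nothing about chance. The highest other split of the interaction had 2894 genes in liver, 9 in kidney and 0 in WAT, and that of the WAT average had 0. For a change of rhythm the highest other of 100 splits had 12 genes in liver, 1 in kidney and 456 in WAT, and for WAT rhythms it had 28 in flox and 978 in iKO. The 2894, 456 and 978 genes point to some structure of the libraries, and which libraries those splits put together was not examined.

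At a single time 6 libraries make 10 splits, too few for a share under 0.05. In liver the real value and the highest other were 0 and 0 at ZT2, ZT10, ZT14 and ZT22, 0 and 7666 at ZT6, and 6 and 0 at ZT18. In kidney they were 0 and 39 at ZT2, 0 and 3042 at ZT6, 0 and 0 at ZT10 and ZT18, 0 and 19 at ZT14, and 2 and 10 at ZT22. In WAT they were 0 and 0 at ZT2, ZT10 and ZT14 and 0 and 1 at ZT6, ZT18 and ZT22. The 7666 liver genes and the 3042 kidney genes came from the split that puts flox ZT6 1 with iKO ZT6 1 and 2. These are the numbers of ZT6 among the 11. At ZT6 this structure of the libraries crosses genotype, but 9 of the 11 are iKO, so it is not separate from genotype.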
